A study of Mus musculus with 5 samples.

How the data were processed

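Total RNA from 5 mouse liver samples, called livers 1 to 5, was measured on 2-colour Agilent 60-mer arrays holding 45018 spots each. Per the labels, the samples came from male C57BL/6N mice given an ethanol diet for 8 weeks and then 3 ethanol binges of 5 g per kg, and liver cDNA carried Cy5 on every array. The Cy3 channel carried a purchased mouse RNA that the labels name as an assorted total RNA and whose tissue they give as liver. All 5 samples form 1 group, and no array had the dyes exchanged. The series was made in parallel with another one, whose diet groups were not analysed here, so no ratio below compares ethanol with a control diet.

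The scanner files hold spot intensity values that the authors obtained with Agilent Feature Extraction 11.5.1.1, per the file headers, as median pixel brightness of each spot and of its local background in both channels, not normalized. The same files hold processed intensities, which per the file headers were background-subtracted, detrended and dye-normalized within the array, and their log10 ratio of Cy5 over Cy3 as deposited. The authors also deposited a table of log2 ratios for 40599 probes. Set against the scanner files, 90.8% of its values lay within 0.001 of the log2 ratio of processed intensities of the same array, which settles its scale and its direction (liver over reference). Its column medians were -0.03, -0.07, -0.08, -0.10 and -0.03 for livers 1 to 5, so it was not centred further. Which rule selected its probes is not given in the sources used here.

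The ratios reported here start from the median intensities, because the files hold no mean intensity for a spot although the plan named it. Background was corrected with normexp (offset 50) on all spots, and each array was normalized by loess with control spots and spots marked as outliers by the scanner software at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and outlier spots were then left out, and spots of one probe were averaged. Between 2.32% and 4.05% of spots per array were left out as outliers. No spot was saturated. Probes were named through their RefSeq accession in an annotation table of assembly GRCm38.p6, since the files pair probes with no gene symbol. Of 41174 probes, 24375 matched a gene and 16799 did not, and 17016 symbols were represented. The file headers name build mm8, so no coordinates are given.

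A probe was tested if it was well above background in either channel on at least 3 of the 5 arrays and had at least 3 values. A gene was represented by its brightest tested probe over both channels, chosen without regard to the ratio. This left 14874 named genes, of which 4571 had more than 1 tested probe. Between 77.3% and 81.2% of spots per array were well above background in Cy5, and between 69.9% and 78.4% in Cy3. The number of arrays limits the precision. Across 181 probes spotted 10 times each and well above background throughout, the median SD between spots of one array was 0.10 (log2) and between livers 0.17.

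The mean log2 ratio was tested against 0 with limma (intercept only, eBayes with intensity trend and robust prior, two-sided). Genes with a Benjamini-Hochberg adjusted p below 0.05 and a ratio of at least 2-fold are called higher or lower. The labels do not say whether the 5 samples are separate animals, so n counts samples, and p-values measure only the spread between these samples, which may be technical. The reference RNA's own spread is left out, and a dye effect of a single probe does not cancel. For 36 gene lists on liver metabolism, stress, liver cell types, blood and other organs, limma's camera (preset correlation 0.01) compared members with all other genes over the 13667 genes with values on all arrays, beside camera with an estimated correlation and fry. With an estimated correlation, camera also uses only the degrees of freedom left by the 5 arrays. A call lost there need not come from correlated members. Spread between livers was tested over the 12014 genes well above background in both channels on all arrays, as an F test of each gene's variance against the intensity-dependent prior variance, upper tail. The SD over livers of each list's mean was set against 10000 random lists of the same size matched on brightness in 20 bins.

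The group, the limma, list and variance tests, the lists, the alternatives other than keeping outlier spots and the rule for naming genes were fixed before the data were examined. The Fisher's exact tests on called genes and some tests of the closing section were chosen after. That rule takes Cyp2b10, the 10 highest and 10 lowest called genes with the same sign and signal well above background in both channels on all arrays, and for each list up to 2 highest and 2 lowest members and the member with the largest SD. It also takes the 10 most variable genes past the variance test. Clone and predicted gene names were skipped. Elovl6, Fasn, Cyp2a5, Cyp4a12a, Ehhadh, Elovl3, Itih3, Apcs and Fgb, called list members outside the rule, and the genes of the closing observations were named after their values were seen. A few genes that the rule takes are not reported here.

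The procedures were tested on simulated data for 13667 genes with the fitted variances of the livers over the reference RNA. Of 200 genes given a log2 ratio of 1.5 in size, 100% were called, and of 12867 unchanged genes 0 were called. With a median SD between livers of 0.19 (log2), the 2-fold limit made both outcomes nearly certain. No dye or cross-hybridisation signal of a single probe was simulated, so the 0 false calls do not cover such signals. The variance test called 0% of 179 genes made 3 times as variable as the trend, 5.11% of 176 made 6 times as variable and 98.8% of 173 made 30 times as variable, so it finds only very large differences between livers. It also called 2 unchanged genes. Camera and the random-list comparison each called the 1 list that had been moved and 0 others. Genes were simulated as independent of each other, whereas on these arrays the acute phase and cholesterol lists each had an estimated correlation of 0.68. The 0 false list calls therefore do not tell how often correlated lists are called wrongly. Alternatives covered background correction, normalization within and between arrays, the filter on dim probes, the variance prior, the summary over probes, the deposited ratios, the thresholds and each liver left out. Keeping the outlier spots was added after seeing the data.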

Results

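The data are 5 two-channel arrays, each setting the RNA of 1 liver sample from the ethanol diet plus binge group against the same reference RNA. Median background-subtracted signal over all probes was between 78.4 and 177 in the liver channel and between 75.5 and 151 in the reference channel. Log2 ratios of pairs of livers correlated across genes with r between 0.39 and 0.75, where genes are not independent replicates. The reference had nearly the same brightness as the livers for core hepatocyte genes, with a median background-subtracted signal of 29918 against 28425 in liver. Probes for brain, muscle, kidney, testis and lung markers were dim in both, at 106 in the reference and 117 in liver. A ratio below therefore describes these livers relative to that RNA, and the effect of ethanol itself was not analysed here.

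The study's title concerns the induction of Cyp2b10, a cytochrome P450 of xenobiotic metabolism controlled by the receptor CAR, by binge drinking. Cyp2b10 stood above the reference in the 4 livers with a usable spot, at a mean log2 ratio of 0.94 ± 0.33 (SD, n = 4), or 1.92-fold, with a limma adjusted p of 0.00294. The log2 ratios were 1.05, 0.90, 0.52 and 1.30 in livers 1, 2, 3 and 5. In liver 4 the Cy5 spot was marked non-uniform and left out, and the processed intensities there gave a log2 ratio of 1.63. The gene has 1 probe on the array, and its background-subtracted signal lay between 1206 and 4090 in liver and between 543 and 1983 in the reference. The mean was just under the 2-fold limit, so Cyp2b10 is not among the genes called higher. It passed that limit with the liver 4 spot kept (1.09), an alternative added after seeing the data, without liver 3 (1.08), in the deposited ratios (1.102) and with arrays scaled to each other (1.03).

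Which genes differed between these livers and the reference was asked across all named genes. The highest and lowest genes given below are those of the naming rule, well above background in both channels on all arrays. Gsta2 (-2.18) and Nudt7 (-1.98), also called lower, did not meet that condition. Hsd3b5, a male-predominant hepatic steroid dehydrogenase, stood lowest, at a log2 ratio of -2.94 ± 0.87 (SD, n = 5), or 7.65-fold lower. Pklr, the liver pyruvate kinase, was at -2.09 ± 0.97, Gstm3, a glutathione transferase, at -1.98 ± 0.40, Me1, the cytosolic malic enzyme that supplies NADPH, at -1.95 ± 0.49, and Lpin1, a phosphatidate phosphatase, at -1.83 ± 0.65. Keg1 at -2.02 ± 0.71, the lipid droplet protein gene Cidec at -1.82 ± 1.21 and the glucose-6-phosphatase gene G6pc at -1.79 ± 1.03 were also among the 10 lowest (n = 5 each). The highest ratio was that of Mycl, which encodes a transcription factor of the Myc family, at 2.29 ± 0.19. Irx3 at 1.96 ± 0.35, Il1f5 at 1.95 ± 0.26, Nhlh1 at 1.91 ± 0.30 and Pou3f4 at 1.88 ± 0.20 were also among the 10 highest (n = 5 each). Haptoglobin (Hp), a plasma protein of the acute phase, stood at 1.81 ± 0.92, with 0.23 in liver 3 and at least 1.79 in each other liver.

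In total, 129 genes were called higher and 62 lower of 14874 tested, and with no minimum ratio 2119 were above and 1901 below the reference. Adjusted p lay between 1.5e-05 for Mycl and 0.0265 for Cidec among these named genes. The calls for Hp, Cidec and G6pc were lost without liver 1 (adjusted p = 0.057, 0.118 and 0.0664), that for Cidec also without liver 3 (0.0615) or 4 (0.0805), and that for G6pc without liver 4 (0.0561). Against a null of 2-fold (limma's treat), 7 genes were higher and 2 lower. Median centring in place of loess gave 97 higher and 77 lower, which moved the higher share from 67.5% to 55.8%.

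The higher and lower genes differed in how far other probes of the same gene bore them out. Of the higher genes, 47 had another tested probe, which pointed the other way for 31 and reached 2-fold for 0. Of the lower genes, 18 had another tested probe, which pointed the other way for 0 and reached 2-fold for 9. Both differences passed Fisher's exact test (two-sided, adjusted over 4 tests, p = 9.68e-07 and 2.03e-06), a comparison chosen after the calls had been seen. Plaat5, at 1.91, had another probe at -0.30, and Kif2a, at 1.80, had other probes at -0.23 and -0.04. Nppb, at -2.38, and Trim35, at -1.88, each had another probe near 0, at -0.11 and -0.11. With all tested probes of a gene averaged, 83 genes were higher and 56 lower, and Plaat5 (0.80), Kif2a (0.51) and Trim35 (-0.99) fell short of 2-fold. Mycl, Irx3, Il1f5, Nhlh1, Pou3f4, Hp, Fxyd3 at 1.80 and Hspa1l at 1.73, the remaining genes of the 10 highest, had no other tested probe.

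Members of the fixed liver and organ lists made up 29 of the 62 lower genes (46.8%) against 3.64% of all tested genes, and 7 of the 129 higher genes (5.43%). Fisher's exact test, also chosen after the calls had been seen, gave adjusted p = 4.94e-25 for the lower and 0.240 for the higher genes. The 7 higher list members were Ahsg, Alb, Apcs, Fgb, Hp, Itih3 and Serpina1e, all genes of plasma proteins made by hepatocytes. The 122 higher genes outside the lists had median log2 ratios of 0.93, 1.57, 1.32, 1.62 and 0.92 in livers 1 to 5. Sequences without a gene symbol showed 240 higher and 18 lower of 10585 tested.

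**Figure D1:**
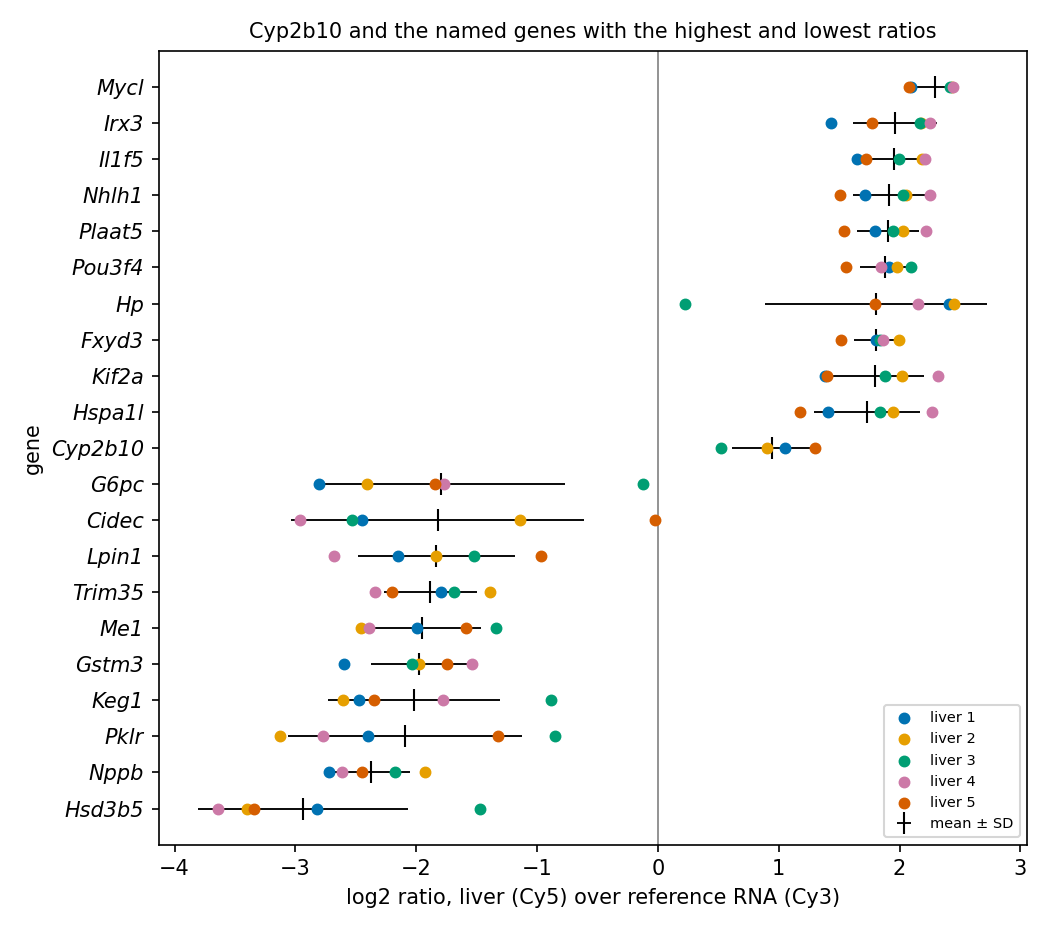
Log2 ratio of liver over reference RNA (x axis) for Cyp2b10 and the 10 highest and 10 lowest genes of the naming rule (y axis). Each liver has 1 point, with the mean as a vertical mark and a bar of 1 SD to each side. The highest and lowest genes are limited to those well above background in both channels on all arrays. Mycl lies between 2.07 and 2.44 in all livers, while Hp ranges from 0.23 to 2.45 and Hsd3b5 from -3.64 to -1.47.

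Gene lists were then compared with all other genes, to see which functions stood apart in the ratio to the reference. Fatty acid and triglyceride synthesis was lower, with 17 of 18 tested members below 0, a median log2 ratio of -0.63 and 7 members called lower, among them Me1, Lpin1, Elovl6 at -1.46, the fatty acid synthase gene Fasn at -1.39 and its regulator Srebf1 at -1.31 (camera adjusted p = 1.78e-05, and adjusted p = 0.642 with an estimated correlation). In cholesterol synthesis and uptake 19 of 19 members were below 0, and Insig1, at -1.31, was called lower (camera adjusted p = 0.0182, and 0.720 as adjusted p with an estimated correlation). Xenobiotic response genes had 6 of 36 members called lower and 0 higher, with Gsta2 at -2.18, Gstm3, Cyp2a5 at -1.62 and Cyp2a4 at -1.60, while Cyp2b10 was the highest member. Camera used the 25 of these members with values on all arrays, which leaves out Cyp2b10 (camera adjusted p = 0.00869, and adjusted p = 0.642 with an estimated correlation). Cyp2a4 and Cyp2a5 are close paralogs, so their probes may share signal. Without liver 1 or 4, Srebf1 (limma adjusted p = 0.0637 and 0.0527) and Elovl6 (0.0893 and 0.0563) were not called. Without liver 5 or with median centring, Cyp2a4 (0.0569 and 0.0543) and Cyp2a5 (0.0628 and 0.0676) were not called. Cholesterol synthesis lost its camera call without liver 2 (adjusted p = 0.0737) or 3 (0.0985).

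Fatty acid oxidation had 4 of 25 members called lower, Acaa1b at -1.70, Pdk4 at -1.19, Cyp4a12a at -1.06 and Ehhadh at -1.03 (camera adjusted p = 0.0147, and adjusted p = 0.642 with an estimated correlation). The lipid droplet list had 2 of 17, Cidec and Fitm1 at -1.12 (0.0328), the NRF2 list 1 of 17, Cbr3 at -1.17, with the transketolase gene Tkt at -0.99 (0.00414), and the periportal list 1 of 12, G6pc (0.0494). Each of these 3 lists had an adjusted p = 0.642 with an estimated correlation. Ethanol and aldehyde oxidation (camera adjusted p = 0.0290, and adjusted p = 0.642 with an estimated correlation) had 10 of 13 members below 0 and 0 called, with Aldh3a2 at -0.87 and the ethanol-oxidising P450 gene Cyp2e1 at 0.12. Lists of Kupffer cells and macrophages (0.0103) and of sinusoidal endothelium (0.00414) were lower with 0 members called, Lyz2 at -0.70, Vsig4 at -0.68 and Ptprb at -0.62 being lowest. With an estimated correlation, both had an adjusted p = 0.642. The camera call was lost for ethanol and aldehyde oxidation without liver 1 (adjusted p = 0.171), for the lipid droplet list without liver 3 (0.0975), with Agilent's processed signals (0.0706) and in the deposited ratios (0.0572), and for the periportal list without liver 1 (0.0908), 3 (0.0992) or 5 (0.0719), with processed signals (0.0521), with scaling between arrays (0.0617) and under the filter on both channels (0.0656). Fitm1 without liver 1 (-0.89), Cbr3 without liver 2 (-0.97), Cyp4a12a without liver 1 (-0.95) or 2 (-0.98) and Ehhadh without liver 1 (-0.92), 2 (-0.96) or 4 (-0.99) fell short of 2-fold.

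Acute phase genes stood higher, with 20 of 22 members above 0 and a median of 0.96 (camera adjusted p = 0.00253, and adjusted p = 0.642 with an estimated correlation). Hp, Itih3 at 1.62 (n = 3), the serum amyloid P gene Apcs at 1.56 and the fibrinogen gene Fgb at 1.29 were called higher, and Hamp2 at -1.48 was called lower. Fgb was not called without liver 1 (limma adjusted p = 0.144), 2 (0.0543) or 5 (0.0906), with median centring (0.0818), with Agilent's processed signals (0.0534) or in the deposited ratios, where it fell short of 2-fold (0.90). Saa1, serum amyloid A, had the highest mean, 1.85 ± 1.56 (SD, n = 5), and was not called (limma adjusted p = 0.0639), but without liver 3 it stood at 2.47 and was called (adjusted p = 0.00418), as it was with scaling between arrays (0.0363) and without trend and robust prior (0.0286). The ER stress list was higher with 15 of 18 members above 0 and 0 called, Chac1 at 0.77 and Ddit3 at 0.60 being highest (camera adjusted p = 0.0273, and adjusted p = 0.642 with an estimated correlation). Brain markers were higher with 10 of 13 above 0 and 0 called (0.0378, and adjusted p = 0.681 with an estimated correlation), Mobp at 0.59 and Snap25 at 0.53 being highest. The brain list's mean was lowest in livers 1 and 5 (0.04 and -0.01), the livers in which the higher genes outside the lists were also lowest. The camera call was lost for ER stress without liver 1 (adjusted p = 0.104) or 5 (0.0888), for brain markers without liver 2 (0.0795) or 3 (0.0841), and for both with Agilent's processed signals (0.0676 each).

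In all, camera called 10 lists lower and 3 higher of 36, and with an estimated correlation it called 0, with 2 lists at an unadjusted p below 0.05. The NRF2 list's estimated correlation was -0.026, yet its unadjusted camera p rose from 0.00046 at the preset correlation to 0.0204. For the periportal list it was -0.015, and p rose from 0.0178 to 0.0695. The loss of these calls thus does not come from correlated members. Fry, which asks whether members move one way and not whether they differ from other genes, called 8, of which 5 were among camera's 13. Adjusted over the list alone, the counts of called members stayed as above except for the lipid droplet list, with 3 lower in place of 2, and bile acid synthesis and transport, with 2 in place of 1.

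Lists that camera did not call held a few called genes. Camera did call neutrophil markers higher without liver 1, 3 or 5, and interferon response (without liver 2 or 4), pericentral (3 or 4) and male-biased genes (4) lower. Other settings also added calls, pericentral and red blood cell genes lower with median centring (adjusted p = 0.0316 and 0.0392), neutrophil markers higher under the filter on both channels (0.0392), embryo markers higher with probes averaged (0.0375) and male-biased genes lower in the deposited ratios (0.0341). With outlier spots kept, core hepatocyte genes were called higher (0.0483) and pericentral (0.0412) and male-biased genes (0.0483) lower. In bile acid synthesis and transport Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -1.30 (n = 4) and called lower, and its call was lost without liver 5 (adjusted p = 0.0591) and with outlier spots kept (0.0665), and its mean fell just short of 2-fold with probes averaged. Among male-biased liver genes Hsd3b5, Nudt7 at -1.98, Elovl3 at -1.65 and Cyp4a12a were called lower and Serpina1e at 1.25 higher. Cyp2a4 was the 1 called member of the female-biased list, Gstm3 of the pericentral list and Col1a1 of the stellate cell and matrix list, where another probe of Col1a1 was at -0.10 and the gene fell short of 2-fold without liver 2 (-0.79) or 3 (-0.94), with scaling (-0.95) and with probes averaged (-0.50). Core hepatocyte genes had a median of 0.23, with Ahsg at 1.72 and Alb, albumin, at 1.15 called higher. Alb fell short of 2-fold without liver 5 (0.97), and Alb (0.75) and Serpina1e (0.92) did so with Agilent's processed signals and in the deposited ratios. In the lists for chemokines, interferon response, neutrophils, lymphocytes, bile duct, p53, cell cycle, circadian clock, glucocorticoid targets, immediate early genes, red blood cells, heart and muscle, kidney, testis, lung, embryo and thymus, 0 members were called. Medians of these lists lay between -0.37 for red blood cells and 0.19 for embryo and fetal markers, and in the lymphocyte, bile duct, testis, lung and thymus lists median and mean had opposite signs.

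The spread between the 5 liver samples was the other quantity measured. Acute phase genes differed most, with a mean log2 ratio over 21 members of 1.30, 1.94, -0.65, 0.75 and 0.79 in livers 1 to 5. Saa1 ran from -0.63 in liver 3 to 3.45 in liver 2, and Lcn2, which encodes lipocalin 2, from -1.26 to 2.38 in the same livers. Glucocorticoid targets moved from -0.93 in liver 3 to 0.76 in liver 2, with Mt1, metallothionein 1, between -1.15 and 2.61. Mt1 and Lcn2 belong to both lists. Fatty acid oxidation genes had means from -0.93 in liver 1 to 0.08 in liver 5, where Fgf21, a hepatic stress hormone, reached 3.31 and Cyp4a14 1.66.

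Cholesterol synthesis genes were highest in liver 1, at 0.31, and lowest in liver 3, at -0.85, with Mvd between -1.72 and 0.73. ER stress genes were highest in liver 5, at 0.82, with Chac1 at 2.37 and Ddit3 at 1.79 there, but this list did not pass with median centring (adjusted p = 0.117). Chemokine, cytokine and adhesion genes were highest in liver 2, at 0.66, with Cxcl1, a neutrophil-attracting chemokine, at 2.53 and the lipopolysaccharide co-receptor gene Cd14 at 1.79. Neutrophil markers were highest in the same liver, at 0.62, with S100a9 at 1.17. Markers of brain (0.43), embryo (0.39), thymus (0.27), testis (0.20), kidney (0.14) and heart and muscle (0.11) were highest there too, while lung markers were not. A high mean in liver 2 was thus not particular to neutrophil markers. Immediate early genes ranged from -0.77 in liver 3 to 0.28 in liver 2, where Egr1 was -1.90 and 1.17. Cdkn1a, a p53 target, lay at -2.69 and -2.41 in livers 4 and 3 and at 0.85 in liver 5.

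The list mean's SD over livers was larger than in matched random lists for 21 of 36 lists after adjustment. It was 0.96 for acute phase genes against a random median of 0.07, 0.70 for glucocorticoid targets, 0.49 for cholesterol synthesis and 0.44 for fatty acid oxidation, each at a p of 1e-04, the smallest that 10000 random lists can give. The lists for circadian clock, cell cycle, NRF2, sinusoidal endothelium, bile duct, periportal, core hepatocyte, male-biased, red blood cell, heart and muscle, kidney, testis, lung, embryo and thymus genes did not pass. Core hepatocyte genes had an SD of 0.14 and NRF2 targets one of 0.05. These p-values are over genes, which are not replicates, and describe these arrays. Gene by gene, the variance test on limma's prior called 0 of 12014, with 665 (5.54%) at an unadjusted p below 0.05 and a smallest adjusted p of 0.327. With median centring it called 217. The list result was lost without 1 liver for ethanol oxidation (liver 1, adjusted p = 0.193), stellate cell and matrix (liver 1, 0.15, or 3, 0.0694), bile acids (2, 0.0956, or 4, 0.0874), lymphocytes (2, 0.054, or 5, 0.126), brain (2, 0.054), fatty acid synthesis (3, 0.0832) and pericentral genes (4, 0.116). With median centring it was lost for lipid droplet (0.983), Kupffer cell (0.386), ethanol oxidation (0.143), stellate cell (0.128), ER stress (0.117), p53 (0.0896) and pericentral genes (0.0896), and gained for male-biased genes (0.0141). It was lost for lymphocytes with processed signals (0.168) and in the deposited ratios (0.177), and for brain in the latter (0.058). Scaling between arrays added periportal (0.0176), male-biased (0.0232) and red blood cell genes (0.0496), leaving out liver 3 or 5 added periportal genes (0.0452 and 0.0494), and keeping outlier spots added male-biased genes (0.0461).

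**Figure D2:**
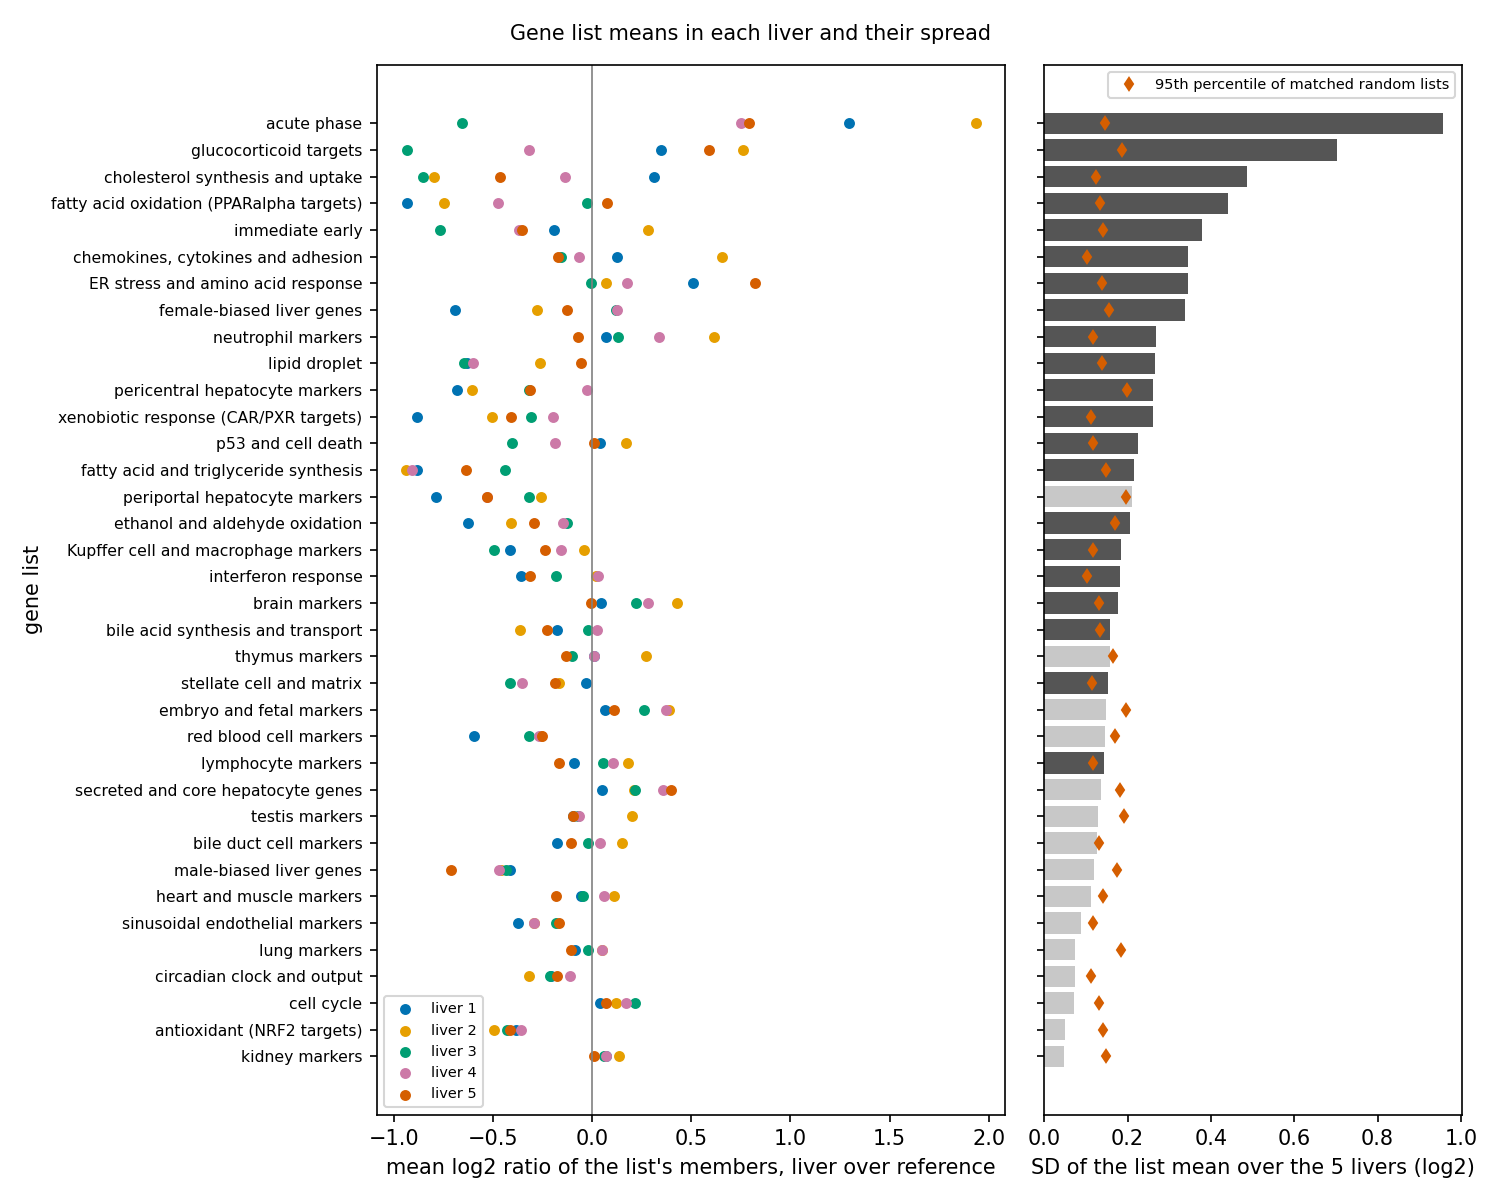
Left, mean log2 ratio (x axis) of each gene list (y axis) with 1 point per liver. Right, SD of that mean over the 5 livers, dark bars passing the comparison with matched random lists and pale bars not, with diamonds at the 95th percentile of the random lists. The acute phase list has the longest bar, 0.96, against a 95th percentile of 0.15.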

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

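The tests on core hepatocyte genes, on background correction, on other probes of the higher genes and on the acute phase genes were chosen after the results they measure had been seen. Those on organ marker detection and olfactory receptor genes were chosen before. In 3 of 36 list means and 6 of 185 named genes, 1 liver lay far from the other 4, judged by its gap to the nearest value as a share of the whole range. Chance marks about 1 in 20 such groups.

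Liver 5 had the lowest male-biased gene mean, -0.71 against -0.47 to -0.41 in the others (gap share 0.807). Liver 1 had the lowest red blood cell mean, -0.60 against -0.32 to -0.25 (0.806). Liver 2 had the highest testis marker mean, 0.20 against -0.10 to -0.07 (0.888). Gbp3 was lowest in liver 1, at -1.10 against -0.61 to -0.45 (0.763). Nkg7, a gene of cytotoxic lymphocytes, was highest in liver 2, at 0.58 against -0.87 to -0.69 (0.871). Gpr182 was lowest in liver 2, at -0.20 against 0.21 to 0.25 (0.914). Ddit3 was highest in liver 5, at 1.79 against 0.05 to 0.48 (0.757), and Alb was highest there too, at 1.87 against 0.78 to 1.08 (0.728). Kdm5d, a Y-linked gene, was highest in liver 3, at 0.51 against -0.02 to 0.12 (0.750).

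Organ markers lay near the reference level although the labels call the reference an assorted RNA. Were it a mixture of several organs, brain, muscle, kidney, testis and lung probes would be detected more often in Cy3. The share well above background on all arrays was 62.8% in Cy3 and 66.0% in Cy5, a difference of -3.19 percentage points. Detection over all spots was also lower in Cy3, at 69.9% to 78.4% per array against 77.3% to 81.2% in Cy5. The organ marker share was not set against that difference, so by itself it argues only weakly against a mixture. The median log2 ratio of core hepatocyte genes was 0.23 and that of organ markers 0.05. Loess pulls the ratios of genes of like brightness towards 0, so these medians by themselves tell little. Before loess, core hepatocyte genes had a median background-subtracted signal of 29918 in the reference and 28425 in liver. Organ markers had 106 and 117. These signals go with both channels holding mainly liver RNA, as the tissue label of the reference also has it. Which diet or age the reference came from stays open.

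Few higher genes were in the fixed lists, 5.43% against 3.64% of all tested genes (Fisher's exact test, adjusted p = 0.240), and no list describes the others. Background correction of dim spots is argued against as the cause for most of them, since 91.5% were well above background in both channels on all arrays, against 80.8% of all tested genes. For the other 11 it stays open, since all 11 kept a mean log2 ratio of at least 1 without background subtraction, but that setting moved the dimmer part of all genes by a median of only 0.0143. Of the higher genes with another tested probe, 66.0% had one pointing the other way, consistent with a signal of the single probe, from dye or cross-hybridisation, rather than of the gene. Genomic DNA in the liver RNA stays open, since 604 olfactory receptor genes stood 0.21 above genes of matched brightness, between the limits set for and against it, while 0.662% of them were called higher against 0.876% of other genes.

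Acute phase genes differed between livers, with liver 3 lowest. A difference between arrays that moves all bright genes is argued against by the core hepatocyte list, of similar brightness, whose SD over livers was 0.162 times that of the acute phase list with median centring, which unlike loess does not flatten such a shift. Fewer leukocytes of all 3 listed kinds in liver 3 are argued against too, since it was lowest in 1 of the 3 leukocyte lists (Kupffer cells and macrophages). At the other end, liver 2 had the highest acute phase mean (1.94) and also the highest mean in all 3 leukocyte lists. These means were 0.62 for neutrophils, -0.04 for Kupffer cells and macrophages and 0.18 for lymphocytes. Markers of brain (0.43), embryo (0.39), thymus (0.27), testis (0.20), kidney (0.14) and heart and muscle (0.11) were highest in liver 2 as well, while lung markers were not. The leukocyte means therefore cannot tell whether liver 2 held more leukocytes, and that explanation stays open. A weaker acute phase response of hepatocytes, the time of sampling, the binge dose received and RNA handling of each liver stay open as untested explanations.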

How the results depend on the processing

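Keeping outlier spots was chosen after seeing the data, and all other alternatives before. Genes higher and lower numbered 317 and 154 with Agilent's processed signals and 323 and 150 in the deposited ratios, of which 118 and 60, and 119 and 57, were among the 129 and 62. They numbered 2119 and 1901 with no minimum ratio, and 7 and 2 with treat against 2-fold, which follow from those thresholds. Averaging all tested probes gave 83 higher genes, all among the 129. Without each replicate in turn, counts ran from 98 to 150 higher and from 54 to 71 lower. Cyp2b10 passed 2-fold at 1.03 with scaling between arrays, 1.102 in the deposited ratios and 1.09 with outlier spots kept, ran from 0.82 to 1.08 without each replicate, and over its 15 alternatives had adjusted p between 0.000299 and 0.0125. It could not be tested under the filter on both channels and all arrays, because of its left-out spot. Camera with an estimated correlation called 0 lists and fry 8, and camera called 11 to 16 without each replicate. Lists moving between livers numbered 18 to 21 without each replicate. Genes past the variance test numbered 217 with median centring and 0 in the other alternatives, where the smallest adjusted p reached at most 0.684. The cause was not tested for the processed signals, the deposited ratios, scaling or median centring. Other counts stayed within 1.5 times.

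The heart muscle gene Myh6, at 0.47 and not called, changed sign where its other probe was used, to -1.79 under the filter on both channels, -1.14 with probes averaged and -1.87 in the deposited ratios, and without each replicate it ran as low as -1.86, with -1.79 and -1.80 in other such fits. Named genes otherwise stayed on their side of the threshold in 2813 cases, lost their call in 47 and gained one in 44. List ratios did so in 542, 18 and 16 cases and list spreads in 549, 20 and 7. The median of all genes stayed between -0.06 and -0.01. No paired analysis was possible because all samples form 1 group. Leaving out saturated spots changes nothing, as no spot was saturated. Slide as a block was not run, since each slide holds 1 array. Signal over background limits dim genes, which the filters left out.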

Other observations

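Y-linked genes lay at the reference level in these male livers. Log2 ratios were -0.04 ± 0.17 for Ddx3y, -0.16 ± 0.18 for Eif2s3y, 0.14 ± 0.21 for Kdm5d and -0.09 ± 0.12 for Uty (SD, n = 5 each), and all 4 were well above background in the reference on all 5 arrays. Xist, the RNA of the inactive X chromosome, was well above background on 0 of 5 arrays in either channel, by its 1 probe. These genes were chosen after the values had been seen.

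Some metabolic genes outside the lists had large differences between livers without passing the variance test, and they too were chosen after their values were seen. Car3, carbonic anhydrase 3, lay at -5.84 in liver 1 and -2.64 in liver 4, against -0.81 to -0.60 in the other livers. Inmt, a methyltransferase gene, was also lowest in liver 1, at -4.61, and lay at -0.45 in liver 3. The uridine phosphorylase gene Upp2 ran from -3.65 in liver 1 to -0.06 in liver 4. Neither gene's mean was called lower (limma adjusted p = 0.0504 for Inmt and 0.0753 for Upp2), but Inmt was in 12 of 16 alternatives (adjusted p from 0.021 to 0.107) and Upp2 in 2 of 16 (0.0352 to 0.148). Among signalling genes, Tifa and Il1r1 were highest in liver 2, at 2.68 and 1.77, and lowest in liver 3, at -1.69 and -1.95.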
